A study of Methanosarcina barkeri str. Fusaro with 54 samples.

How the data were processed

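RNA was sequenced from 54 libraries of the methanogenic archaeon Methanosarcina barkeri Fusaro, in 18 groups of 3. Per the labels, cells were taken in mid-exponential growth after at least 30 generations in their medium, RNA was purified with TRIzol and a column kit, 16S and 23S rRNA was removed by subtraction, and ScriptSeq libraries were read for 101 cycles on a HiSeq2000 and demultiplexed with Casava 1.8.2. Per the file headers, trimmed single reads that an earlier mapping had left unmapped were counted per gene. The aligner, its version and the annotation source were not given in the sources used here, nor whether counting used the strand, so antisense reads and overlapping genes cannot be told apart.

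The deposited tables hold raw read counts per gene, with and without reads that map to several places, for 3625 genes, of which 3607 lie on the chromosome and 18 on the plasmid. The authors also deposited RPKM values, used here only to recover the mapped total of 52 libraries. The deposited signed fold changes and p-values come from the authors' EDGE test. They are quoted where named and were not used in any fit. The deposited positions of the counted regions, given from the first base of each replicon, are the coordinates printed here. A second location column matched the counted region for 1063 genes, and it was not used. The sheets that repeat excerpts of the full tables were not used.

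Gene reads ranged from 0.579 M to 15.8 M per library, with a median of 6.25 M, and 97.4% to 98.7% of them were unique to 1 place. Groups were taken from the strain and medium in the labels. The labels carry no replicate numbers, so replicates were numbered by title order, and they do not say whether replicates were separate cultures. Replicates 2 and 3 of Pyr-2 with all substrates have titles that share a number and were kept as 2 libraries. The p-values therefore measure the spread between these samples. Floors cover counting error only. The SE of a log2 fold change was derived from the F statistic of its test, which includes the spread between libraries.

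Counts were fitted in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, and the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Each medium was fitted with its 9 libraries, the 15 DSMZ804 libraries were fitted together for comparisons between media, and the 45 libraries of DSMZ804, Pyr-1 and Pyr-2 were fitted jointly for the mean over 5 media and for the 8 coefficients of the strain by medium interaction. CPM scale each library's gene reads to the same total, and those named TMM-scaled use edgeR's library factors. The common biological coefficient of variation was 0.299 to 0.405.

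Of 24 gene lists fixed by product name, 23, each with at least 3 tested members, were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated one. The lists for pyruvate:ferredoxin oxidoreductase and for pyruvate carboxylase and related enzymes are the study's own question, so their direction is not independent evidence. The list for stable RNA matched only 10 protein-coding genes and was left out, so removal of stable RNA could not be tried.

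The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Mbar_A1588, Mbar_A2165 and every member of the 2 pyruvate lists. For the mean over media, the constructed strains and the DSMZ804 media it adds the 8 highest and 8 lowest log2 fold changes among called genes of at least 3 mean log2 CPM. Those genes must not overlap between groups, or for the mean must go the same way in all 5 media. Within a medium it takes the 4 highest and 4 lowest, and from every other list the 2 largest rises and 2 largest falls among called members. Not every gene it allows is printed, and genes outside it are said to be so.

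The alternatives were size factors by RLE, DESeq2 1.42.0 with its Wald and likelihood-ratio tests, no filter on counts, unique reads, each library left out in turn, 2 Pyr-2 libraries whose titles share a number summed as 1, and an estimated correlation for the lists. The count column headers name a lane code for each library, 5 in all, unevenly spread over strains and media. Some libraries share both a code and an index sequence, which a single lane could not tell apart, so a code can stand for several runs. Sequencing lane here means this code, and a fit with it does not adjust for the run. After the data had been seen, 8 more were added: leaving out 2 DSMZ804 libraries with plasmid reads, counting 1 of them as Pyr-1, each of 2 title series alone, title series as a covariate, sequencing lane as a factor, the correlation of reads with gene length as a covariate, and the lists in acetate without 1 DSMZ804 library. The method was tested on simulated data with 200 changed genes per fit. Within a medium edgeR recovered 6.87% to 36.1% of 2-fold changes and 72.2% to 90.4% of 4-fold changes, against 92.8% and 100% for the mean over media. Genes were simulated independently around pooled means, without title series or differences in library profile, so these rates may not hold for the real libraries. In the simulated acetate data DESeq2 made 40 false calls among 201, so its counts are given beside those of edgeR and not in their place. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.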

Results

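Transcript levels were measured by RNA sequencing in the methanogen Methanosarcina barkeri Fusaro. The strain DSMZ804 is the wild type, and Pyr-1 and Pyr-2 are cell lines of a strain named Pyr+ for its growth on pyruvate. These 3 strains were grown in low-salt medium with acetate (120 mM), methanol (125 mM), methanol and acetate, methanol and pyruvate (100 mM), or all 3 substrates, with 3 libraries per group. The constructed strains WWM85, WWM818 and WWM940 were grown in high-salt (HS) medium with 125 mM methanol, also with 3 libraries each. Gene reads per library ranged from 0.579 M to 15.8 M.

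The hpt gene Mbar_A1633, chromosome 2015011 to 2015583, which the labels give as deleted in WWM85 and the strains made from it, was nearly silent in the constructed strains. It stood at 0.685 ± 0.430 CPM in WWM85, 1.27 ± 0.503 in WWM818 and 0.528 ± 0.263 in WWM940 (SD, n = 3 each). The means of the other 15 groups lay between 158 and 195 CPM, with 172 ± 30.7 (SD, n = 3) for DSMZ804 in methanol.

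The plasmid separated DSMZ804 from the other strains. Its 14 genes other than transposases together gave 0.869 to 119 CPM in 13 of the 15 DSMZ804 libraries, with a median of 3.40. They gave 753 to 3172 CPM in the 15 Pyr-1 libraries and 696 to 2646 in the 15 Pyr-2 libraries. The constructed strains held more, with 6131 to 9263 CPM in WWM85, 3801 to 5286 in WWM818 and 4100 to 8932 in WWM940. The library labelled DSMZ804 acetate replicate 3 (3012 CPM) and the library labelled DSMZ804 methanol-acetate replicate 1 (1332 CPM) stood with the Pyr+ lines.

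**Figure D1:**
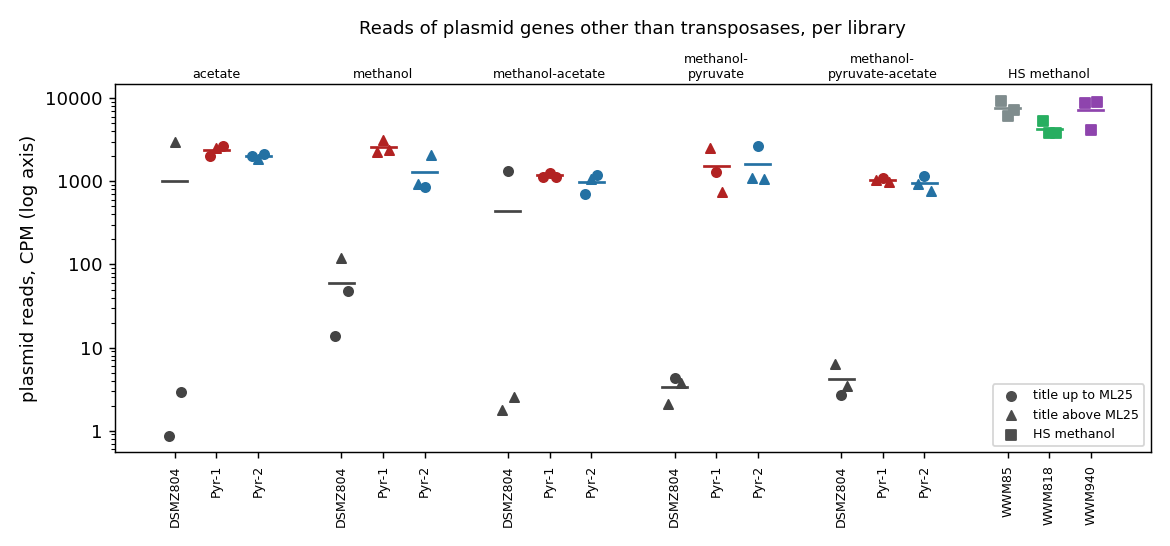
Summed CPM of the 14 plasmid genes other than transposases in each library, on a log axis, by strain and medium, with bars for group means. Of the 15 DSMZ804 libraries, 13 lie at or under 119 CPM, and the other 2 lie at 1332 and 3012 CPM among the Pyr+ lines.

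Over the 5 media, Pyr-1 against DSMZ804 asks what sets this Pyr+ line apart whatever the substrate. The genes of pyruvate:ferredoxin oxidoreductase, which interconverts pyruvate with acetyl-CoA and CO2, rose together. Their products are annotated as the beta subunit (Mbar_A0999, 1220851 to 1221741), alpha subunit (Mbar_A1000, 1221738 to 1222946), delta subunit (Mbar_A1001, 1222946 to 1223233) and gamma subunit (Mbar_A1002, 1223230 to 1223778). Phosphoenolpyruvate carboxylase (Mbar_A2632) and pyruvate carboxylase subunit A (Mbar_A1587), which make oxaloacetate, also rose. So did Mbar_A2165 (2739467 to 2740342), a gene of unstated function that WWM940 carries in a G59R form.

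The alpha subunit gene Mbar_A1000 averaged 2764 ± 2646 TMM-scaled CPM in Pyr-1 and 693 ± 554 in DSMZ804 (SD, n = 15 each), a log2 fold change of 1.94 ± 0.43 (SE, adjusted p = 0.0118). The other subunit genes gave 1.90 ± 0.44 for Mbar_A0999 (adjusted p = 0.0199), 2.41 ± 0.57 for Mbar_A1001 (adjusted p = 0.0209) and 2.44 ± 0.53 for Mbar_A1002 (adjusted p = 0.00936). For all 4 genes the fitted change was above 0 in each of the 5 media. Mbar_A2632 was 2.83-fold higher (adjusted p = 0.00259), at 712 ± 516 against 253 ± 195 TMM-scaled CPM (SD, n = 15 each). On the log2 scale Mbar_A1587 rose by 1.16 ± 0.29 (adjusted p = 0.0322) and Mbar_A2165 by 0.98 ± 0.24 (adjusted p = 0.0277). Leaving out 1 library ended the call of Mbar_A1587 in 15 of 30 fits (adjusted p up to 0.124), of Mbar_A2165 in 8 (up to 0.116) and of Mbar_A1001 in 5 (up to 0.139), in each case with Pyr-1 methanol replicate 1 among them. It ended that of Mbar_A0999 in 4 (up to 0.116), of Mbar_A1000 in 2 (up to 0.0707) and of Mbar_A1002 in 1 (0.0669), always without a replicate 1 of Pyr-1, and that of Mbar_A2632 in 0. In titles above 25 alone, however, Mbar_A2632 gave 0.34, Mbar_A1587 0.41 and Mbar_A2165 0.22 (adjusted p from 0.951 to 0.963). With the sequencing lane as a factor Mbar_A1000 (2.28, adjusted p = 0.0187), Mbar_A2632 (1.82, 0.00410) and Mbar_A1587 (1.33, 0.0291) were called, and Mbar_A0999 (1.81, 0.0657), Mbar_A1001 (2.32, 0.134), Mbar_A1002 (2.55, 0.0501), Mbar_A2165 (0.93, 0.135) and Mbar_A3404 (0.73, 0.108) were not. Pyruvate carboxylase subunit B, Mbar_A1586, gave 0.67 and the biotin ligase gene Mbar_A1588 gave 0.58, with adjusted p = 0.227 and 0.162. Mbar_A3404, subunit K of the F420H2 dehydrogenase, which passes electrons from reduced coenzyme F420 to the membrane, rose by 0.82 ± 0.17 (adjusted p = 0.00725), but it was not called in titles up to 25 alone (0.94, adjusted p = 0.0542) or above 25 alone (0.74, 0.494). The 3 genes that fell encode hypothetical proteins, at -0.88 for Mbar_A1686, -0.46 for Mbar_A3578 and -0.35 for Mbar_A1314, each with adjusted p = 0.0459, and leaving out 1 library ended their calls in 20, 20 and 19 of 30 fits.

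In all, edgeR called 41 genes, 38 higher and 3 lower, and 18 of these were the plasmid genes. This count moved to between 24 and 110 without 1 library, to 130 without both doubted libraries, to 449 in titles up to 25 alone, to 20 in titles above 25 alone and to 184 with title series as a covariate. The plasmid genes Mbar_B3759, Mbar_B3749 and Mbar_B3753, the last a mannosyltransferase, had log2 fold changes of 6.12, 5.66 and 5.65, each averaged over the log2 changes of the 5 media. In the pyruvate:ferredoxin oxidoreductase list 4 of 13 members rose over all genes tested and 5 adjusted over the list alone, and the list was higher (adjusted p = 0.00249, and adjusted p = 0.823 with an estimated correlation). The members outside the 4 subunit genes, such as the indolepyruvate oxidoreductases and the phosphoenolpyruvate synthases of the related list, gave -0.10 to 0.35. In the pyruvate carboxylase list 2 of 14 rose, and 3 adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.823 with an estimated correlation). Neither of these lists, being the study's own question, is independent evidence. No ribosomal protein gene passed the test singly, yet 58 of 60 lay above 0 with a median of 0.40 (adjusted p = 0.00105, and adjusted p = 0.840 with an estimated correlation). Replicate 1 of Pyr-1 in the media with methanol had a Spearman's rho between reads and gene length of 0.614 to 0.721, below every DSMZ804 library except those of methanol replicates 1 and 2 (0.704 and 0.643). Oxidative stress (adjusted p = 0.0343), C1 pathway (0.0112) and transcription and translation genes (0.0472) were higher as lists, and methylamine (0.0393) and surface protein genes (0.0112) lower. None of these 5 calls held with an estimated correlation, where adjusted p = 0.823 or 0.840. In the libraries with title numbers above 25, which cover 4 of the media and include the doubted acetate library, 20 genes were called, and the 4 subunit genes gave 0.42 to 0.91, with adjusted p from 0.910 to 0.963. Up to title number 25 they gave 2.68 to 3.73, all called.

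**Figure D2:**
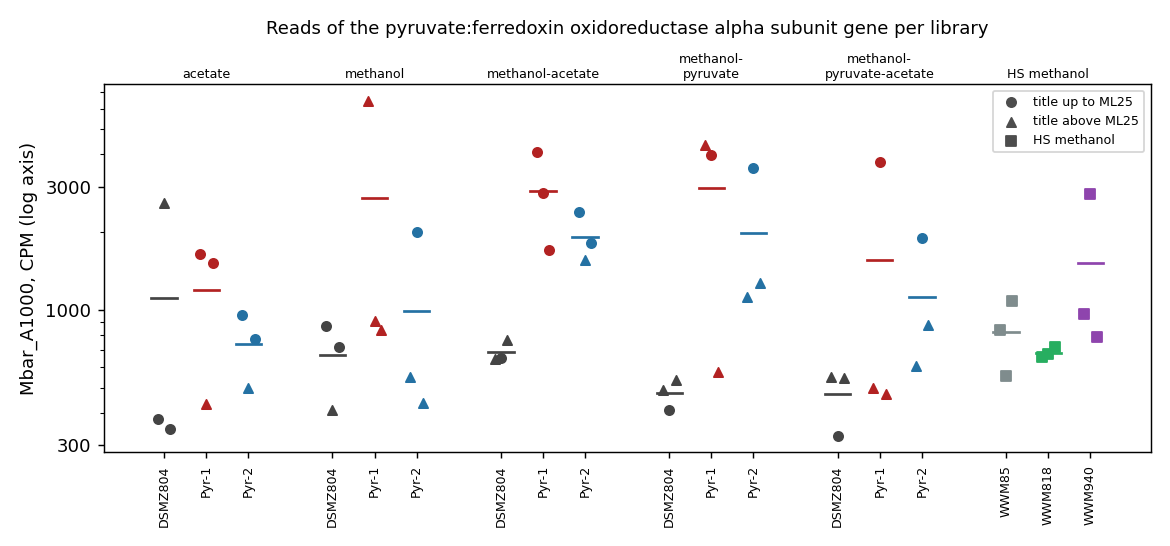
CPM of the pyruvate:ferredoxin oxidoreductase alpha subunit gene Mbar_A1000 in each library, on a log axis, by strain and medium, with bars for group means. Circles mark titles up to 25, triangles titles above 25 and squares HS medium. In methanol-acetate the Pyr-1 libraries reach 4083, 2835 and 1706 CPM for Mbar_A1000, against 650, 648 and 764 in DSMZ804.

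Pyr-2 over the 5 media shared the plasmid signal, and its changes in chromosomal genes were few. The plasmid genes Mbar_B3759, Mbar_B3749 and the ORC/Cdc6 gene Mbar_B3760, named for replication initiation proteins, rose by 5.80, 5.40 and 4.91 on the log2 scale. Mbar_A3221, an ArsR family transcriptional regulator, fell from 242 ± 116 to 146 ± 29.8 TMM-scaled CPM (SD, n = 15 each), a log2 fold change of -0.70 ± 0.15 (SE, adjusted p = 0.0126). The subunit genes of pyruvate:ferredoxin oxidoreductase gave 0.92 for Mbar_A1000 to 1.33 for Mbar_A1002, with adjusted p = 1.00 and 0.940, and none was called. Mbar_A2632 gave 0.91 (adjusted p = 0.405).

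edgeR called 21 genes in Pyr-2, 20 higher and 1 lower, 18 of them on the plasmid. The chromosomal genes that rose, chosen after their values were seen, encode hypothetical proteins, Mbar_A1108 (0.64, adjusted p = 0.0476) and Mbar_A3373 (0.68, adjusted p = 0.0170). The list of pyruvate:ferredoxin oxidoreductase genes was higher (adjusted p = 0.0267), gas vesicle genes were higher (0.00682) and methylamine genes lower (0.0267), each with adjusted p = 0.786 with an estimated correlation. Chaperone genes were lower (0.0372). Of the mobile element genes 4 rose, all plasmid transposase genes already counted above, and the test pointed up (0.0267), while their median was -0.02. For both lists adjusted p = 0.985 with an estimated correlation. In titles above 25 alone 35 genes were called. A fit with the sequencing lane as a factor called 60, 13 of them among the 21, and neither Mbar_A3221 (-0.69, adjusted p = 0.0962) nor Mbar_B3760 (0.0650) among them. Mbar_A3221 was also not called in titles up to 25 or above 25 alone (adjusted p = 0.820 and 0.101). Without the doubted DSMZ804 acetate replicate 3 Mbar_A2632 was called (adjusted p = 0.0291), and without both doubted libraries it was not (0.0519). In titles up to 25 alone all 4 subunit genes of pyruvate:ferredoxin oxidoreductase were called, at 1.70 to 2.35, and in titles above 25 alone none was, at 0.10 to 0.47.

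Both lines shared 18 genes that were higher against the same DSMZ804 libraries, and all 18 were plasmid genes. Independent lists would share 0.21. In 40 simulations of unchanged groups, where both lines were compared with the same simulated DSMZ804 libraries, they shared at most 0. Genes were simulated independently and without title series, so this does not measure what structure in the real libraries could add. With the DSMZ804 libraries divided between the lines the shared count was 17 or 18. No gene was lower in both. Once the sequencing lane was a factor, the lines shared 14, 12 higher and 2 lower.

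Pyr-1 and Pyr-2 were compared with each other over the 5 media to ask where the lines differ. The pyruvate:ferredoxin oxidoreductase subunit genes were 0.76 to 1.13 higher in Pyr-1 on the log2 scale, with adjusted p from 0.538 to 0.549. edgeR called 0 genes, with 335 at an unadjusted p under 0.05, and DESeq2 called 8. With the sequencing lane as a factor edgeR called 392, so this count depends on how the lanes are treated. Methanol methyltransferase genes, which start methanogenesis from methanol, were higher as a list in Pyr-1 (median 0.82, adjusted p = 0.00333), as were ribosomal protein genes (59 of 60 above 0, adjusted p = 1.81e-06), and surface protein genes were lower (0.00062). All 9 lists that passed had adjusted p = 0.789 with an estimated correlation. In the 4 media with methanol, replicate 1 of Pyr-1 had a rho between reads and gene length of 0.614 to 0.721 and 9.40% to 12.7% of reads in 10 genes, against 0.726 to 0.803 and 4.87% to 6.53% in replicate 1 of Pyr-2.

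The interaction asks whether strain differences depended on the medium. edgeR called 1 gene, Mbar_A1482 (1829533 to 1830351), which lies outside the naming rule and was chosen after its values were seen. It stood at 11518 ± 18972 CPM in DSMZ804 in methanol (SD, n = 3) and at means of 154 to 305 in the other groups of these strains, and DSMZ804 methanol replicate 2 alone carried it (adjusted p = 0.0205, and 1.00 without that library). At an unadjusted p under 0.05 there were 124 genes, and DESeq2 called 13. For the subunit genes of pyruvate:ferredoxin oxidoreductase and for Mbar_A2632 the interaction gave adjusted p = 1.00, so a difference between media in their change was not shown.

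In acetate, the changes of the subunit genes of pyruvate:ferredoxin oxidoreductase depended on the doubted DSMZ804 replicate 3. With it they gave in Pyr-1 log2 fold changes of 0.09 to 0.53 and in Pyr-2 of -0.38 to -0.67, and Mbar_A1000 stood at 1223 ± 728 TMM-scaled CPM in Pyr-1, 722 ± 266 in Pyr-2 and 1147 ± 1319 in DSMZ804 (SD, n = 3 each). The DSMZ804 mean rested on replicate 3, with 2601 CPM against 380 and 345 in the other DSMZ804 libraries, 432 to 1644 in Pyr-1 and 499 to 955 in Pyr-2. Without it the genes gave 1.23 to 2.30 in Pyr-1 (adjusted p = 0.881) and 0.60 to 1.33 in Pyr-2 (0.962), none called. Methylamine genes, which serve growth on methylamines, were lower as a list in Pyr-1 (median -0.65, adjusted p = 1.22e-05, and adjusted p = 0.255 with an estimated correlation) and in Pyr-2 (median -0.78, adjusted p = 6.51e-06, and adjusted p = 0.251 with an estimated correlation). Nitrogen fixation genes were lower in Pyr-1 (adjusted p = 0.00225, and adjusted p = 0.277 with an estimated correlation), and ribosomal protein genes were lower in Pyr-2 (median -0.50, adjusted p = 2.19e-15, and adjusted p = 0.371 with an estimated correlation). Without DSMZ804 replicate 3 the medians were -0.35 and -0.56 for methylamine genes (adjusted p = 0.0169 in Pyr-1 and 0.0118 in Pyr-2) and -0.18 for ribosomal protein genes in Pyr-2 (0.0305), with adjusted p from 0.825 to 0.931 with an estimated correlation, and the nitrogen fixation call ended (0.365). The profiles also differ, with 6.57%, 6.84% and 4.47% of reads in 10 genes in DSMZ804 against 3.53%, 3.59% and 2.17% in Pyr-2, whose replicate 3 had a rho of 0.920 between reads and gene length against 0.788 and 0.778 in the others. Between the lines, cobalamin (adjusted p = 0.0225) and phosphate transport genes (1.40e-08) were higher in Pyr-1, both with adjusted p = 0.202 with an estimated correlation.

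edgeR called 0 genes in acetate for Pyr-1, for Pyr-2 and between the lines, with 73, 65 and 10 at an unadjusted p under 0.05, and DESeq2 called 0 in each. Without DSMZ804 acetate replicate 3 it called 16 genes for Pyr-1 and 17 for Pyr-2, all on the plasmid, and with the sequencing lane as a factor 15 and 17. The lane fit is not a separate check, because the lane of that replicate holds no other library in acetate.

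In methanol alone, the plasmid genes were the called difference. In Pyr-1 Mbar_B3746 reached 183 ± 29.5 TMM-scaled CPM against 2.87 ± 2.85 in DSMZ804 (SD, n = 3 each), a log2 fold change of 6.07 (adjusted p = 0.0385), and the transposase genes Mbar_B3756 and Mbar_B3743 rose by 5.31 and 4.74. In Pyr-2 Mbar_B3759 rose by 4.90 (adjusted p = 0.00359) and Mbar_B3749 by 4.38 (adjusted p = 0.0429). Mbar_A1000 gave 2.04 in Pyr-1 (adjusted p = 0.725), where the libraries held 6430, 904 and 839 CPM, and 0.24 in Pyr-2. Methanol methyltransferase genes were lower as a list in Pyr-2 (median -2.03, adjusted p = 0.00184, and adjusted p = 0.749 with an estimated correlation), and metal transport genes higher (adjusted p = 0.000494, and 0.749 with an estimated correlation). The groups differ in profile and title series: Spearman's rho between reads and gene length was 0.704, 0.643 and 0.898 in DSMZ804, with 6.39%, 17.1% and 1.82% of reads in the 10 most abundant genes, and 0.758, 0.873 and 0.891 in Pyr-2, with 4.87%, 2.14% and 2.00%. Titles above 25 held 1 DSMZ804 and 2 Pyr-2 libraries.

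The counts were 13 genes for Pyr-1 and 2 for Pyr-2, all higher and all on the plasmid. Between the lines edgeR called 0, with 310 at an unadjusted p under 0.05, and DESeq2 called 86. In Pyr-1 mobile element genes were higher as a list (2 of 90 rose, and 5 adjusted over the list alone; adjusted p = 8.41e-08, and 0.822 with an estimated correlation), and oxidative TCA genes lower (adjusted p = 0.0155, and 0.822 with an estimated correlation). Leaving out single libraries gave 1 to 15 genes for Pyr-1 and 0 to 4 for Pyr-2, and in titles above 25 alone, with a single DSMZ804 library, both counts were 0. They were 0 and 4 with the sequencing lane as a factor.

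With methanol and acetate together, Pyr-1 differed from DSMZ804 in more chromosomal genes than in any other medium, though the number of calls was not tested between media. Mbar_A2011 (2537125 to 2539170), a hypothetical protein gene, rose from 431 ± 54.5 to 33668 ± 17829 TMM-scaled CPM (SD, n = 3 each), a log2 fold change of 6.29 ± 0.70 (SE, adjusted p = 0.00985). The methanol corrinoid protein gene Mbar_A3637 rose by 4.32 and its methyltransferase partner Mbar_A3638 by 3.42, with adjusted p = 0.0482 and 0.0391. Stress genes rose with them, by 3.91 for the Hsp20 chaperone gene Mbar_A0859, 2.68 for the small heat shock gene Mbar_A1892, 3.54 for the thioredoxin peroxidase gene Mbar_A0479 and 2.60 for superoxide dismutase Mbar_A3589. The pyruvate:ferredoxin oxidoreductase genes rose by 2.44 for Mbar_A1000 (adjusted p = 0.0320) to 3.11 for Mbar_A1001 (0.0320).

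Among enzymes around pyruvate, Mbar_A2632 rose by 2.04 and the phosphoenolpyruvate synthase gene Mbar_A3094 by 1.26, both with adjusted p = 0.0320, and Mbar_A2165 by 1.83 (adjusted p = 0.0205). Pyruvate carboxylase Mbar_A1587 gave 1.63 and Mbar_A1588 gave 1.20, with adjusted p = 0.0729 and 0.0622. The Ech hydrogenase genes Mbar_A0149 and Mbar_A0148, whose enzyme couples ferredoxin to hydrogen, rose by 1.43 and 1.36, and the ATPase subunit I gene Mbar_A0391 by 1.80. Also higher were a cobalamin biosynthesis gene, Mbar_A2565 (2.16), and a phosphate transporter gene, Mbar_A1778 (2.12). Genes that fell include Mbar_A3497 (-1.72), Mbar_A1943 (-1.62), the transposase Mbar_A2638 (-1.24), the cobalamin gene Mbar_A2145 (-1.09) and the monomethylamine corrinoid protein gene Mbar_A0845 (-0.99). For each of these called genes the 3 libraries of Pyr-1 did not overlap those of DSMZ804, which the naming rule required of the genes taken by size. The groups also differed in library profile and title series. Spearman's rho between reads and gene length was 0.614 to 0.743 in Pyr-1 and 0.788 to 0.818 in DSMZ804, the 10 most abundant genes took 6.51% to 11.5% and 2.54% to 2.97% of reads, and all 3 Pyr-1 libraries but 1 of DSMZ804 had titles up to 25. With title series as a covariate 6 genes were called, and of the genes named here Mbar_A2011 alone. The subunit genes of pyruvate:ferredoxin oxidoreductase then gave 2.29 to 2.53 (adjusted p from 0.0882 to 0.151), Mbar_A2632 2.23 (0.0882) and Mbar_A2165 1.51 (0.0708). With the correlation of reads with length as a covariate 2 were called, of the named genes again Mbar_A2011 alone, the subunit genes gave 1.33 to 1.74 (0.454 to 0.917), Mbar_A2632 1.41 (0.999) and Mbar_A2165 1.13 (0.422).

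By list in Pyr-1, 4 of 8 methanol methyltransferase genes rose over all genes and 5 adjusted over the list alone (adjusted p = 1.77e-08, and adjusted p = 0.288 with an estimated correlation). So did 6 of 26 chaperone genes, and 11 adjusted over the list alone (1.26e-07, and 0.348 with an estimated correlation). In the oxidative stress list 4 of 18 rose, and 8 adjusted over the list alone (1.13e-05, and 0.348 with an estimated correlation). In the hydrogenase and electron transfer list 2 of 52 rose, and 16 rose and 2 fell adjusted over the list alone (0.00917, and 0.504 with an estimated correlation). In the pyruvate:ferredoxin oxidoreductase list, the study's own question, 5 of 13 rose by either count (0.00104, and 0.348 with an estimated correlation). Of the C1 pathway genes 0 of 38 passed and 21 rose and 2 fell adjusted over the list alone (4.29e-06, and 0.450 with an estimated correlation). All 60 ribosomal protein genes lay above 0, with none called (median 1.07, adjusted p = 1.51e-07, and 0.504 with an estimated correlation). These lists moved between groups that differ in rho, at 0.614 to 0.743 against 0.788 to 0.818.

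edgeR called 73 genes for Pyr-1, 60 higher and 13 lower, none on the plasmid, with 1099 at an unadjusted p under 0.05, and DESeq2 called 653. In 28.9% of genes the groups did not overlap, against a chance share of 10%. For Pyr-2 edgeR called 0, with 281 at an unadjusted p under 0.05 and 43 by DESeq2. In Pyr-2 Mbar_A1000 gave 1.58 (adjusted p = 0.441) and Mbar_A2632 gave 1.53 (0.275), and gas vesicle genes were higher as a list (0 of 3 rose, and 3 adjusted over the list alone; median 5.36, adjusted p = 3.56e-07, and 0.370 with an estimated correlation). Between the lines edgeR called 0, with 98 at an unadjusted p under 0.05 and 13 by DESeq2. Without the doubted DSMZ804 replicate 1 the counts were 1591 for Pyr-1 and 632 for Pyr-2. The DSMZ804 libraries left then all had titles above 25, and the Pyr-1 libraries all had titles up to 25. Strain and title series cannot be told apart in that count for Pyr-1. Without DSMZ804 replicate 2 or 3 the Pyr-1 count was 0. Titles up to 25 held all 3 Pyr-1 libraries and, of DSMZ804, replicate 1 alone, and gave 0 genes for Pyr-1.

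With methanol and pyruvate, plasmid genes were again the calls. Mbar_B3759 (27473 to 28123 on the plasmid) stood at 39.2 ± 18.8 CPM in Pyr-1 and 52.8 ± 31.8 in Pyr-2 (SD, n = 3 each). It had 0 reads in the DSMZ804 libraries, so it was at least 111-fold higher in Pyr-1 and at least 150-fold higher in Pyr-2, against a floor of 3 reads per library. The plasmid transposase gene Mbar_B3743 rose by 6.04 in Pyr-1 and 6.27 in Pyr-2. The subunit genes of pyruvate:ferredoxin oxidoreductase gave 2.74 for Mbar_A0999 to 3.90 for Mbar_A1002 in Pyr-1 (adjusted p = 0.736) and 2.09 to 2.95 in Pyr-2 (adjusted p = 0.999), and Mbar_A1002 stood at 1020 ± 821 and 528 ± 587 TMM-scaled CPM against 68.2 ± 21.2 in DSMZ804 (SD, n = 3 each). Mbar_A2632 gave 2.10 and 1.89.

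The counts were 15 genes for each line, all higher and all on the plasmid. Between the lines edgeR called 0, with 42 at an unadjusted p under 0.05, and DESeq2 called 0. Of the pyruvate:ferredoxin oxidoreductase genes of Pyr-1 none was called over all genes and 5 of 13 rose adjusted over the list alone, which is not independent evidence (adjusted p = 0.0322, and 0.889 with an estimated correlation). Ribosomal protein genes were higher as a list in Pyr-1 (58 of 60 above 0, adjusted p = 6.24e-08, and 0.889 with an estimated correlation) and in Pyr-2 (59 of 60, 1.48e-13, and 0.760). Replicate 1 of Pyr-1 stood apart, with a rho of 0.701 between reads and gene length and 12.7% of reads in 10 genes, against 0.801 and 0.874 in the other Pyr-1 libraries and 0.799 to 0.856 in DSMZ804. Without single libraries the counts were 5 to 18 for Pyr-1 and 6 to 15 for Pyr-2, with the lowest without DSMZ804 replicate 2. In titles above 25 alone, with 2 libraries per group, they were 0, as they were with the sequencing lane as a factor, a fit that compares the replicate 1 libraries because each other lane holds 1 strain in this medium.

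With all 3 substrates, plasmid genes were once more the calls. Mbar_B3753 stood at 30.0 ± 4.82 CPM in Pyr-1 and 25.9 ± 6.59 in Pyr-2 (SD, n = 3 each) and had 0 reads in DSMZ804, so it was at least 62.5-fold and at least 53.9-fold higher. Mbar_B3743 rose by 7.36 and 7.25. The pyruvate:ferredoxin oxidoreductase genes gave 2.09 for Mbar_A1000 to 2.98 for Mbar_A1002 in Pyr-1 (adjusted p = 0.977), where replicate 1 held 3728 CPM of Mbar_A1000 and the others 501 and 473. They gave 1.33 to 2.15 in Pyr-2 (adjusted p = 1.00).

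Each line had 17 called genes, all higher and all on the plasmid. Between the lines edgeR called 0, with 9 at an unadjusted p under 0.05, and DESeq2 called 0. When the sequencing lane was a factor, the counts were 892, 99 and 173 for Pyr-1, Pyr-2 and between the lines, from a fit that compares the 3 replicate 1 libraries, since each other lane here holds 1 strain. Of these, Pyr-1 replicate 1 stood apart, with a rho of 0.721 between reads and gene length and 9.40% of reads in 10 genes, against 0.859 and 0.862 in replicates 2 and 3 and 0.818 to 0.858 in DSMZ804. Pyr-2 replicate 1 had a rho of 0.803 and 6.50% of reads in 10 genes. The share was 2.13% and 2.25% in the other Pyr-2 libraries and 2.24% in DSMZ804 replicate 1. In Pyr-1 all 60 ribosomal protein genes lay above 0 (adjusted p = 3.51e-08, and 0.678 with an estimated correlation), and in Pyr-2 C1 pathway genes were higher as a list (adjusted p = 0.00366, and 0.924 with an estimated correlation).

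The authors' deposited test gave folds on its own scale, positive where the second group was higher. For Mbar_A1000 in Pyr-1 it lists a fold of 1.07 in acetate, 4.13 in methanol, 4.09 in methanol-acetate, 7.71 in methanol-pyruvate and 4.25 with all substrates. Its methanol-acetate comparison files the library labelled DSMZ804 replicate 1 under Pyr-1. It lists 1726 genes at an unadjusted p under 0.05 there.

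The HS strains ask what pycC1, which the labels add in WWM818, and then Mbar_A2165 in its G59R form, added in WWM940, did to the transcripts. In WWM940 the subunit genes of pyruvate:ferredoxin oxidoreductase stood higher than in WWM818 by 1.44 for Mbar_A1001 to 1.61 for Mbar_A0999 on the log2 scale (adjusted p = 0.999), and Mbar_A1000 averaged 1842 ± 1801 against 647 ± 30.2 TMM-scaled CPM (SD, n = 3 each). Replicate 2 of WWM940 carried the mean, with 2817 CPM against 963 and 788. Mbar_A2165 itself stood at 199 ± 102, 127 ± 17.4 and 115 ± 42.2 TMM-scaled CPM in WWM940, WWM818 and WWM85 (SD, n = 3 each). Pyruvate carboxylase Mbar_A1587 gave 0.78 in WWM940 against WWM818 and -0.12 in WWM818 against WWM85. Mbar_A1000 gave -0.34 in WWM818 against WWM85 (adjusted p = 0.980) and 1.16 in WWM940 against WWM85 (0.919).

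edgeR called 0 genes in WWM818 against WWM85, in WWM940 against WWM818 and in WWM940 against WWM85, with 82, 53 and 93 at an unadjusted p under 0.05, and DESeq2 called 8, 5 and 2. As lists in WWM940 against WWM818, all 60 ribosomal protein genes lay above 0 (median 1.38, adjusted p = 1.62e-20), and pyruvate:ferredoxin oxidoreductase (6.98e-06), acetoclastic (0.000880) and aspartate family genes (1.26e-06) were higher and CRISPR genes lower (0.00644). All of these had adjusted p = 0.374 with an estimated correlation. WWM940 replicate 2 stood apart, with a Spearman's rho between reads and gene length of 0.723 against 0.870 and 0.895 in the other WWM940 libraries and 10.2% of reads in its 10 most abundant genes against 2.53% and 2.24%, and the lists were not tested without it. In WWM818 against WWM85 ribosomal protein genes were lower (median -0.42, adjusted p = 0.000190), as were branched-chain amino acid genes (0.00502), with adjusted p = 0.872 with an estimated correlation.

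Within DSMZ804, the media were compared to ask how levels differ with acetate or pyruvate beside methanol. Methanol methyltransferase genes were lower as a list with methanol and acetate against methanol (median -1.64, 0 of 8 fell and 4 adjusted over the list alone, adjusted p = 0.00666) and with acetate against methanol (median -1.54, adjusted p = 9.01e-05). The former comparison holds the doubted methanol-acetate replicate 1 and the latter the doubted acetate replicate 3. The lists were not tested without them here. ATP synthase genes were higher in the same comparisons (adjusted p = 0.00666 and 0.000560), and with an estimated correlation neither list passed, with adjusted p = 0.598 in the former comparison and 0.551 in the latter. The methanol libraries differed among themselves, with a rho between reads and gene length of 0.704, 0.643 and 0.898 and 6.39%, 17.1% and 1.82% of reads in 10 genes, while rho was 0.771 to 0.831 in acetate and in methanol-acetate and 0.799 to 0.856 in methanol-pyruvate. Ribosomal protein genes were lower with methanol and pyruvate than with methanol (median -1.25, adjusted p = 2.95e-17, and 0.548 with an estimated correlation). They were also lower with all substrates than with methanol and acetate (adjusted p = 1.88e-25, and 0.680 with an estimated correlation) and than with methanol and pyruvate (1.59e-07, and 0.686). Mbar_A1000 stood at 467 ± 22.3 TMM-scaled CPM with methanol and pyruvate and 800 ± 403 with methanol (SD, n = 3 each), a log2 fold change of -0.78 (adjusted p = 0.573).

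edgeR called 0 genes in each of the 6 comparisons between media. At an unadjusted p under 0.05 there were 497 for methanol-acetate against methanol, 368 for methanol-pyruvate against methanol, 71 for all substrates against methanol-acetate, 25 for all substrates against methanol-pyruvate, and 183 each for methanol-acetate against acetate and for acetate against methanol. In the same order DESeq2 called 35, 24, 0, 0, 1 and 11. No list passed for methanol-acetate against acetate. Without DSMZ804 methanol replicate 3 the counts against methanol were 26, 112 and 25, for methanol-acetate, methanol-pyruvate and acetate. Titles above 25 alone, with 1 methanol library and of acetate only the doubted one, gave 1098, 86 and 270 for these and 884 for methanol-acetate against acetate, and titles up to 25 alone gave 120 for acetate against methanol. Without both doubted libraries methanol-acetate against acetate had 65.

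Reads followed gene length more closely in some libraries than in others. Spearman's rho across genes, which are not independent replicates, had a median of 0.855 in the 24 libraries with title numbers above 25 and of 0.762 in the 21 up to 25. It was higher above 25 in each of the 13 groups that hold both, by 0.0925 on average. A one-sided permutation test within groups gave p = 1e-05, the smallest its 100000 permutations can give. The cut at 25 and the direction of the test were chosen after the data had been seen. The 10 most abundant genes took a median of 6.53% of reads up to 25 and 2.34% above.

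**Figure D3:**
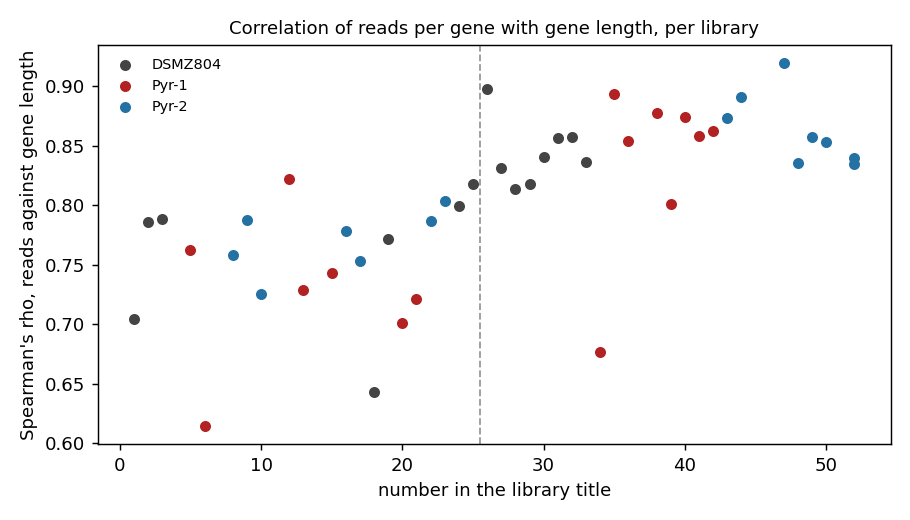
Spearman's rho between reads and gene length in each of the 45 libraries of DSMZ804, Pyr-1 and Pyr-2 (y axis, no unit) against the number in the library's title (x axis). The dashed line stands between 25 and 26, and the medians on its sides are 0.762 and 0.855.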

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

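The tests of strain labels, mixture, genomic DNA, title series, lane and library profile, and the splits of the libraries, were chosen or read only after the results were seen, whereas the interaction test was planned.

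The strain difference of Mbar_A1482 differed between media by the interaction test (adjusted p = 0.0205), with DSMZ804 in methanol at 402 to 33424 CPM and the highest other group mean of these strains at 305. Without DSMZ804 methanol replicate 2 the adjusted p was 1.00, and it was 0.0651, 0.117 and 0.115 without Pyr-1 methanol replicate 1, 2 or 3, 0.115 and 0.117 without Pyr-2 methanol replicate 2 or 3, 0.420 with the correlation of reads with length as a covariate and 1.00 with the sequencing lane as a factor. Of the 100 splits drawn, 30 called as many genes as the real interaction, 1, and the highest other called 1568, and of 100 drawn within title series 32 did, with a highest of 241, so chance cannot be excluded.

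Outside transposase genes, the libraries labelled DSMZ804 acetate replicate 3 and DSMZ804 methanol-acetate replicate 1 held 3012 and 1332 CPM of plasmid reads. The other 13 DSMZ804 libraries held at most 119. A scale with DSMZ804 at 0 and Pyr+ at 1 was set over 50 chromosomal markers, picked in 6 acetate libraries with titles up to 25. The acetate library, not used to pick them, lay at 1.34, so a wrong strain label is a candidate explanation. The other DSMZ804 acetate libraries lay at -0.394 and 0.283 and Pyr+ acetate libraries at 0.583 to 1.33. Except for replicate 3 of Pyr-1 and of Pyr-2, at 0.583 and 0.680, these libraries served to pick the markers. Their separation was therefore fixed by that choice. The methanol-acetate library lay at 0.0508, beside -0.0149 and 0.0147 for the other DSMZ804 libraries and 0.695 to 1.43 for Pyr+. In other media the scale did not separate the strains, with Pyr-1 all-substrate replicate 3 at -0.568 and DSMZ804 methanol replicate 2 at 0.647. The methanol-acetate library thus lay with DSMZ804 in its own medium, which goes against a wrong label but does not settle it. The authors' methanol-acetate comparison files this library under Pyr-1, while their DSMZ804 data hold the same counts under DSMZ804. The plasmid reads of this library would need a mixture with 123% Pyr+ RNA like the mean of the Pyr+ libraries in its medium. Mbar_A2011 and the pyruvate:ferredoxin oxidoreductase genes allowed at most 25.2%, which argues against a mixture with such cells. These levels differed among Pyr+ libraries of other media, with plasmid reads up to 3172 CPM in Pyr-1 in methanol. A mixture with Pyr+ cells in another state is therefore not excluded. A DSMZ804 culture that kept the plasmid was not tested and stays open for both.

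Reads followed gene length more closely in the 24 libraries with title numbers above 25 than in the 21 up to 25, in all 13 groups that hold both. The mean difference within groups of 0.0925 goes with the title number, so a difference between library series is a candidate explanation, although the labels name no batch. The count column headers give 5 lane codes, and with group and lane code as terms the title series term was 0.0962 ± 0.0327 (SE). Because a code can stand for several runs, this cannot decide whether the lane or run is the cause. Genomic DNA would need to make 65.4% of reads in the later Pyr+ libraries, whose plasmid read density was 21.8% of the chromosomal median (n = 16) against 34.9% in the earlier ones (n = 14). In the later libraries a median of 24.2% of 2575 genes, and at least 13.2% (n = 24), lay below the read density that evenly spread DNA at that share would give, which goes against it. It cannot be told apart from other causes, because how evenly DNA would be read is not known, because 14.8 plasmid copies per 100 chromosomes would give that density and the copy number is unknown, and because the share of mapped reads in genes (56.3% later, 60.7% earlier) depends on whether counting used the strand. No biological explanation was tested, and growth stage or culture date stay open.

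The pyruvate:ferredoxin oxidoreductase genes rose in Pyr-1 over the 5 media, and the fitted rise was larger in the earlier title series. With the correlation of reads with length as a covariate Mbar_A0999, Mbar_A1000 and Mbar_A1002 gave 1.09, 1.17 and 1.56 and were still called (adjusted p = 0.0278, 0.0412 and 0.0265), and with title series as a covariate all 4 genes gave 1.55 to 2.03 and were called, which argues against a shift common to all strains by either as the whole cause. With the sequencing lane as a factor Mbar_A1000 gave 2.28 ± 0.52 and was called (adjusted p = 0.0187). This cannot decide whether the lane is the cause for this gene, because a lane code can stand for several runs. Mbar_A0999, Mbar_A1001 and Mbar_A1002 gave 1.81 ± 0.48, 2.32 ± 0.69 and 2.55 ± 0.65, against 1.90 ± 0.44, 2.41 ± 0.57 and 2.44 ± 0.53 without that factor. Their calls ended (0.0657, 0.134 and 0.0501) as the SE grew, so the lane cannot be told apart from the strain for them. With the reads-length covariate the change of Mbar_A1001 went from 2.41 ± 0.57 to 1.21 ± 0.38 (SE) and the adjusted p from 0.0209 to 0.104 because the change shrank, so the steepness of the profile and the strain cannot be told apart for this gene. In titles above 25 alone, over 4 media, the 4 genes gave 0.42 to 0.91 and none was called. In the 3 media with both series in both strains they gave 2.77 to 4.11 up to title 25 and -0.74 to 0.07 above, so that fit shows no rise in the later series, while in 2 media without the doubted libraries they gave 0.62 to 1.81 above. The change up to title 25 exceeded that above by 2.95 to 4.84 on the log2 scale (edgeR adjusted p from 0.0594 to 0.0880), and without the doubted libraries, in 2 media, by 2.29 to 4.14 (0.179 to 0.307), so the difference was called for none of the 4 genes. A strain difference that shows under some culture or library conditions may account for this, remains a hypothesis, and was not tested further.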

How the results depend on the processing

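Settings that leave out or regroup the libraries with plasmid reads, use 1 title series alone, or take title series, the sequencing lane or the reads-length correlation into the fit were chosen only after the data had been seen. Of 29 counts, 2 stayed within 1.5 times under every alternative run, Pyr-1 against Pyr-2 in methanol-pyruvate and DSMZ804 with all substrates against methanol-pyruvate, both 0. For single genes, 5835 alternatives of 235 results gave 5370 on the same side of the threshold, 444 weaker, 21 stronger and 0 of opposite direction. No filter, unique reads and the summed pair of Pyr-2 libraries kept every count within 1.5 times, as did RLE except for Pyr-2 in methanol (1). Where a setting moved a value the cause was not tested, except that fewer libraries were fitted where libraries were left out. Unique reads were not run with all substrates or jointly, because 2 Pyr-2 libraries lack them, and removal of stable RNA and a pseudocount were not run, nor was leaving out libraries for the lists, except for DSMZ804 acetate replicate 3 in acetate. Titles above 25 could not be fitted in acetate, nor titles up to 25 in methanol-pyruvate and with all substrates, and Pyr-1 had no library up to 25 in methanol or above 25 in methanol-acetate. No paired analysis was possible because the labels carry no replicate numbers and the numbers used here follow title order. For plasmid genes with 0 reads in DSMZ804 depth limits the fold to a lower bound.

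DESeq2 gave 34, 24 and 86 genes in methanol (Pyr-1, Pyr-2, Pyr-1 against Pyr-2), 653, 43 and 13 in methanol-acetate, 24 for Pyr-1 in methanol-pyruvate, 8, 5 and 2 for WWM818 against WWM85, WWM940 against WWM818 and WWM940 against WWM85, 35, 24, 1 and 11 in DSMZ804 (methanol-acetate and methanol-pyruvate against methanol, methanol-acetate against acetate, acetate against methanol), and for the mean 77 for Pyr-1, 8 between the lines and 13 for the interaction. With an estimated correlation 0 lists passed, against 199 with the preset one, over all comparisons. Without the libraries with plasmid reads the counts were 16 and 17 in acetate, 1591 and 632 in methanol-acetate, 65 and 1 in DSMZ804 (methanol-acetate against acetate, acetate against methanol), 130 for the Pyr-1 mean and 12 for the interaction. With the methanol-acetate library counted as Pyr-1 they were 1381 and 260 in methanol-acetate and 99 for the Pyr-1 mean.

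Titles up to 25 alone gave 31, 29 and 1 in acetate, 33 for Pyr-2 in methanol, 0 for Pyr-1 in methanol-acetate, 1 and 120 in DSMZ804 (methanol-pyruvate and acetate against methanol), and 449 for the Pyr-1 mean and 9 between the lines over 4 media. Titles above 25 alone gave 0 and 0 in methanol, with 1 DSMZ804 library, and in methanol-pyruvate, 1607 for Pyr-2 in methanol-acetate, 1098, 86, 2, 884 and 270 in DSMZ804 (methanol-acetate and methanol-pyruvate against methanol, all substrates against methanol-acetate, methanol-acetate against acetate, acetate against methanol), and 20 and 35 for the means of Pyr-1 and Pyr-2. The count of 1607 rests on 1 Pyr-2 library, methanol-acetate replicate 3. With title series as a covariate Pyr-2 in methanol had 4, methanol-acetate 6 and 4, the Pyr-1 mean 184, which kept all 41, the lines 12 and the interaction 2. With the reads-length correlation as a covariate Pyr-2 in methanol had 9, methanol-acetate 2 and 3, the Pyr-2 mean 34, the genes shared by both lines 28 and the interaction 0. With the sequencing lane as a factor the counts for Pyr-1 and Pyr-2 were 15 and 17 in acetate, 0 and 4 in methanol, 0 and 0 in methanol-pyruvate and 892 and 99 with all substrates, where the lines differed in 173. In methanol-pyruvate and with all substrates that fit compares replicate 1 libraries, since each other lane there holds 1 strain. In acetate it in effect leaves out DSMZ804 replicate 3, the only library of its lane there. In methanol-acetate the lane could not be fitted. The Pyr-1 mean had 33, 29 of them among the 41, the Pyr-2 mean 60, the lines 392, the interaction 0 and both lines shared 14, 12 higher and 2 lower.

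Leaving out 1 library at a time gave, for Pyr-1 and Pyr-2, 0 to 16 and 0 to 17 in acetate (highest without DSMZ804 replicate 3), 1 to 15 and 0 to 4 in methanol, 0 to 1591 and 0 to 632 in methanol-acetate (highest without DSMZ804 replicate 1, and for Pyr-1 0 without DSMZ804 replicate 2 or 3, and 15 and 30 without Pyr-1 replicate 1 or 2), and 5 to 18 and 6 to 15 in methanol-pyruvate. In methanol the Pyr-1 count was 3 without DSMZ804 replicate 2, 2 without Pyr-1 replicate 1 or 3 and 1 without Pyr-1 replicate 2, and the Pyr-2 count 0 without DSMZ804 replicate 2, 4 without DSMZ804 replicate 3 and 1 without any other. In methanol-pyruvate the counts were 7 and 8, 5 and 6, and 8 and 9 without DSMZ804 replicate 1, 2 or 3. WWM940 against WWM818 gave 0 to 1 (without WWM940 replicate 2), and DSMZ804 0 to 26, 0 to 112 and 0 to 25 for methanol-acetate, methanol-pyruvate and acetate against methanol (without methanol replicate 3), and 0 to 2 for methanol-acetate against acetate (without acetate replicate 3). The Pyr-1 mean gave 24 to 110: 24 without Pyr-1 methanol or all-substrate replicate 1, 25 without Pyr-1 methanol-acetate or methanol-pyruvate replicate 1, 27 without DSMZ804 methanol-acetate replicate 2, 64 without DSMZ804 methanol-pyruvate replicate 1, 69 without either doubted library and 110 without Pyr-1 methanol-pyruvate replicate 3. Between the lines it gave 0 to 7: 1 without Pyr-1 methanol replicate 2 or all-substrate replicate 2 or 3, 3 without Pyr-1 methanol replicate 3, 4 without Pyr-2 methanol-acetate replicate 2 and 7 without Pyr-1 methanol-pyruvate replicate 3. The interaction gave 0 to 6: 0 without the libraries that end the call of Mbar_A1482, 3 and 6 without DSMZ804 acetate replicate 1 or 3, and 2 and 5 without DSMZ804 methanol replicate 1 or 3. Over single omissions for the Pyr-1 mean, Mbar_A0999 lost its call without Pyr-1 replicate 1 of methanol (adjusted p = 0.0942), methanol-acetate (0.0529), methanol-pyruvate (0.0818) or all substrates (0.116), Mbar_A1000 without that of methanol (0.0707) or all substrates (0.067), Mbar_A1002 without that of all substrates (0.0669), Mbar_A1001 in 5 fits (up to 0.139), without these replicates 1 or DSMZ804 methanol-acetate replicate 2, Mbar_A2165 in 8 (up to 0.116), without replicate 1 of Pyr-1 in any medium, DSMZ804 methanol-acetate replicate 2 or 3 or methanol-pyruvate replicate 3, and Mbar_A1587 in 15 (up to 0.124), without any of the same 8 or DSMZ804 acetate replicate 1 or 2, methanol replicate 1 or 3, methanol-pyruvate replicate 2 or all-substrate replicate 2 or 3. Mbar_A2632 lost it in 0 of these, and in titles above 25 alone it gave 0.34 with adjusted p = 0.956, within a range of 2.018e-05 to 0.956 over all alternatives.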

Other observations

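The split counts, the levels of the gas vesicle genes in single libraries and those of Mbar_A2011 were chosen or read only after the data had been seen.

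Gas vesicle genes, whose products form gas-filled compartments that give buoyancy, varied from library to library. Mbar_A0326 to Mbar_A0328 together held 785 to 13099 CPM in the Pyr-2 methanol-acetate libraries, 366 to 7825 in Pyr-2 with all substrates and 130 to 8083 in Pyr-2 acetate, a 62.0-fold range between libraries of 1 group. DSMZ804 with all substrates held 430 to 6461 and with methanol and pyruvate 131 to 4614, and Pyr-1 with methanol and pyruvate held 190 to 7284. In the HS strains they stayed between 100 and 141 CPM and in DSMZ804 in methanol between 61.1 and 127. As lists they were higher in Pyr-2 in acetate (median 2.02, adjusted p = 0.00368, and 0.335 with an estimated correlation) and lower in Pyr-1 than in Pyr-2 with all substrates (median -3.44, adjusted p = 5.85e-13, and 0.103 with an estimated correlation). DSMZ804 in acetate held 2179 CPM in the doubted replicate 3 and 81.9 and 60.6 in the others. Without that replicate the Pyr-2 median in acetate was 5.48 (adjusted p = 0.0172, and 0.825 with an estimated correlation).

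The hypothetical protein gene Mbar_A2011 also differed between libraries of 1 group. It held 28381 ± 9982 CPM in Pyr-1 and 17190 ± 3371 in Pyr-2 with methanol and acetate against 471 ± 50.9 in DSMZ804 (SD, n = 3 each), but DSMZ804 in methanol held 1148 to 31887 CPM. In acetate DSMZ804 held 422 and 456 CPM, and 12989 in the doubted replicate 3. The HS strains held means of 522 to 548 CPM. Its methanol-acetate call in Pyr-1 was lost without DSMZ804 replicate 2 or 3 (adjusted p = 0.137 and 0.125) and in titles up to 25 alone (0.274), where fewer libraries were fitted, with log2 fold changes of 6.45, 6.39 and 6.58 against 6.29 with all libraries. Over the 5 media, outside the naming rule, it gave 3.08 ± 0.71 (SE, adjusted p = 0.0189), and 3.39 ± 0.91 with the sequencing lane as a factor, not called (0.0697).

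Pyr-1 replicates 2 and 3 with all substrates were the closest of the 54 pairs of replicates, with a chi-square of 3.38 per degree of freedom against a next value of 6.19 and a median of 192.

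The 6 libraries of a comparison within a medium make 10 splits into 3 and 3, too few for a share under 0.05. In acetate, in HS medium and between the lines in methanol and with all substrates the real count and the highest other were 0, so 10 of 10 splits gave as many. For DSMZ804 between media the real counts were 0, again equalled by 10 of 10, and the highest others were 840, 710, 0, 0, 469 and 82 in the order methanol-acetate and methanol-pyruvate against methanol, all substrates against methanol-acetate and against methanol-pyruvate, methanol-acetate against acetate, and acetate against methanol. For Pyr-1 and Pyr-2 with all substrates the real count was 17 and the highest other 0 (1 of 10). It was 15 and 0 for Pyr-2 in methanol-pyruvate (1 of 10) and 73 and 0 for Pyr-1 in methanol-acetate (1 of 10). For Pyr-1 in methanol-pyruvate it was 15 and 1194 (2 of 10), and in methanol 13 and 1609 for Pyr-1 and 2 and 981 for Pyr-2 (2 of 10 each). For Pyr-2 in methanol-acetate it was 0 and 737, and between the lines 0 and 62 in methanol-pyruvate and 0 and 2 in methanol-acetate (10 of 10 each). The split with 981 set DSMZ804 replicates 1 and 2 with Pyr-2 replicate 1, and that with 737 set DSMZ804 replicate 1 with Pyr-2 replicates 1 and 2, which are the libraries with titles up to 25 in each case. Those with 1609 and 1194 set the libraries up to 25 together with 1 Pyr-1 library above 25. Splits that call several times the real count point to a structure of the samples. Of the 100 splits drawn over the 5 media, 3 gave as many genes as Pyr-1 (41, highest other 1287) and 3 as many as Pyr-2 (21, highest other 259), and the highest splits again point to structure. Those splits exchanged libraries across title series. Of 100 splits drawn within medium and title series, the real one alone, 1 of 100, gave as many genes as Pyr-1 (highest other 1) and as many as Pyr-2 (highest other 1). Plasmid genes made up 18 of the 41 and 18 of the 21, so this does not test single chromosomal calls. Lanes were not kept, and chance is not excluded for those calls. Only the real split, 1 of 100, gave 18 genes in both lines by either draw (highest other 1 in each). Between the lines the real count was 0, which 100 of 100 splits reach whatever they show (highest other 1261), so they decide nothing there. In titles above 25 alone the counts were 20 and 35.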
